A study of Mus musculus with 2 samples.

How the data were processed

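RNA of mouse heart was compared with RNA of mouse embryonic fibroblasts (MEF), cultured connective-tissue cells from embryos, on 2 two-colour Agilent oligonucleotide arrays. Per the labels, heart RNA was labelled with Cy3 and MEF RNA with Cy5 on both arrays, the hearts were numbered 1 and 2 and were not cultured, and total RNA was extracted with TRIzol and purified on columns. Neither array had the dyes exchanged, so a bias of a probe for one dye stays in its ratio. The labels do not say whether the hearts came from separate animals, nor whether the MEF RNA was one preparation. The p-values below therefore measure the spread between these 2 arrays, which may be technical, and leave out the spread between MEF cultures.

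The authors deposited one value per probe and array for 41174 probes, read here as the log2 ratio of the 2 channels. Per the submitters' processing notes the scanner images were read with Agilent Feature Extraction; the version, the background correction, the normalization and any filter are not given in the sources used here. The channel intensities were not used here, so neither signal over background nor saturation of a probe could be judged, and no level of one probe can be set against another. No value was missing and none was exactly 0. The log base is not stated. The largest absolute value, 11.62, would be a ratio of 3150 on the log2 scale, of 111441 as a natural logarithm and of 4.181e+11 as log10, while a 16-bit scanner's largest reading is 65535. The values were therefore taken as log2. The medians were 0.07 on the heart-1 array and -0.14 on the heart-2 array, so the deposited values were not centred on the median; what centring was applied stays unknown.

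The direction of the ratio is not stated either. By a rule fixed before the data were examined, it was read from a list of cardiac sarcomere genes, whose median was 6.29 on the heart-1 array and 6.30 on the heart-2 array. Positive values are accordingly taken as heart over MEF throughout. This direction is likely rather than stated; Feature Extraction's own ratio is Cy5 over Cy3, which would carry the opposite sign. The direction of the sarcomere list itself is not a result.

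Probes were named from the platform annotation. Of the 41174 probes, 32664 had 1 gene symbol, 45 had several and 8465 had none here. The gene identifiers of 32524 of the 32664 were found in a table of RefSeq genes of assembly GRCm38.p6, and no symbol needed updating. Probes of a gene were averaged per array, giving 19532 genes, of which 8511 had more than 1 probe. The probes of 3324 of these (39.1%) disagreed in the sign of their mean, and the median range between the probes of a gene was 0.95 on the log2 scale. Coordinates are not given because no genome build is named for the values.

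The mean log2 ratio of each gene was tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit on an intercept, eBayes, Benjamini-Hochberg adjusted p under 0.05); tables were joined in Python 3.11.15. The 2 arrays leave 1 residual degree of freedom, so the test leaned on the variance shared across genes (prior standard deviation 0.066, 1.25 prior degrees of freedom). All adjusted p-values of genes are from this test, two-sided. The smallest it gave was 0.00136, shared by many genes, so sizes rather than p-values rank the genes. Errors are the SD of the 2 arrays and do not cover the spread between the probes of a gene. Probe ranges are given below for some genes only, and others can be as wide. The probe means of Xirp2, for example, ran from 5.06 to 8.90. There were 37 gene lists fixed before the data were examined, with 1022 entries, of which 954 were measured. Each was tested with limma's camera at its preset correlation of 0.01, adjusted over the 37 lists, and its members were counted at the gene test's threshold.

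Genes named in the text were chosen by a rule fixed at the same time: the 15 highest and 15 lowest genes that passed and had one sign on both arrays, without clone-type symbols; up to 4 members of each list with the largest absolute mean and up to 3 against its majority; a set of key genes whatever their values; and the 5 genes with the largest difference between the hearts in each direction. Any other gene is said to have been chosen after its values were seen. Values of a few marker genes were looked at while the scale was being settled, before any test was run but after the lists and rules were fixed.

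The fit was tested on simulated data drawn from the same prior for 19532 genes. With few genes changed, the test called 0% of 66 genes changed by 1 on the log2 scale, 67.2% of 67 changed by 2 and 82.1% of 67 changed by 4, with 5 of 19332 unchanged genes called. With 14283 genes changed by the sizes estimated here, it called 89.5% of them, and 1.17% of its calls were unchanged genes. The simulated unchanged genes had a true ratio of exactly 0, without dye bias or an offset of the zero. The changed genes were those already called in the real data. These shares therefore do not give the error among the real calls. In simulated lists, 0 of 36 random ones passed. Genes were drawn independently of each other there, so correlation between the genes of a list was not covered. Alternatives covered the centring and scaling of the arrays, the variance prior, a test against a 2-fold change, the treatment of probes, other list tests and each array alone. A filter on values at exactly 0 or at a limit of the scale was planned but had nothing to remove.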

Results

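The study compared gene expression in mouse heart with that in mouse embryonic fibroblasts. It held 2 arrays, each pairing one heart RNA (heart-1 or heart-2) with MEF RNA as the reference channel. With MEF as the reference on both arrays and no MEF sample measured against it, the log2 ratio against 0 was the comparison. Precision is limited by the number of arrays. The log2 ratios ran from -11.38 to 11.27 on the heart-1 array and from -11.62 to 11.22 on the heart-2 array, with SDs of 1.67 and 1.68 over all probes. Both arrays also held a narrow spike of near-constant values, between 0.1 and 0.2 on heart-1 with 5367 probes and between -0.22 and -0.08 on heart-2 with 6271 probes, against a median of 211 and 210 probes per bin of width 0.02 around it.

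**Figure D1:**
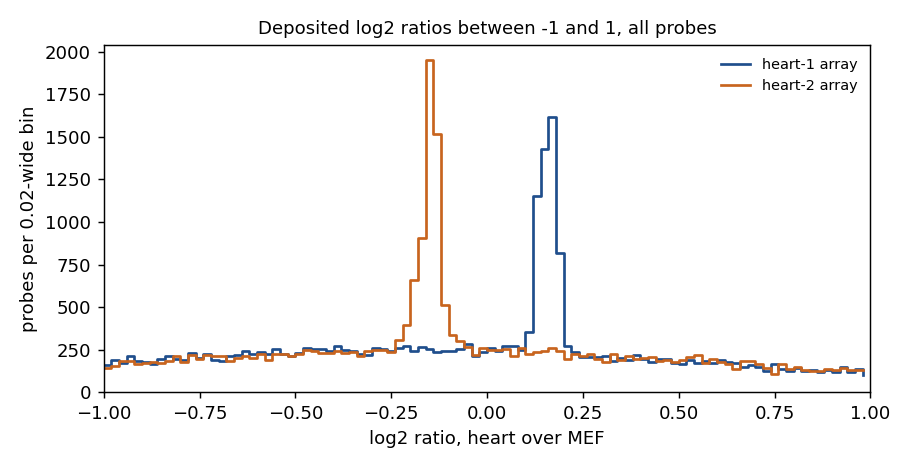
Number of probes (y axis) in bins of 0.02 of the log2 ratio of heart over MEF (x axis), between -1 and 1, for the 2 arrays (lines). The spike lies above 0 on heart-1, centred at 0.16, and below 0 on heart-2, centred at -0.15.

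The heart arrays gave closely similar ratios. Across the 19532 genes the Pearson correlation between arrays was 0.982 and the Spearman correlation 0.959; genes are not independent replicates, and the MEF reference contributes to both arrays. The SD of the difference between arrays was 0.32 on the log2 scale, against an SD of 1.68 for the mean ratio over genes, and 91.8% of genes differed by less than 0.5.

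Tested against no difference, 14283 of 19532 genes (73.1%) were called, 6598 higher and 7685 lower in heart, and the mean of 6765 of them was under 2-fold. Calls of that size depend on where the ratio's zero lies and on dye bias, which are not known here. Among all genes, 7140 were at least 2-fold apart on both arrays, 3526 higher and 3614 lower in heart, and 7120 of these passed the test. At least 4-fold on both arrays were 1756 higher and 1407 lower genes. Against a 2-fold change, limma's treat called 5797 genes, 2947 higher and 2850 lower. Without the variance shared across genes, which leaves 1 degree of freedom, 6131 genes were called.

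The 15 highest ratios lay between 8.45 and 11.24. Pln, which encodes phospholamban, the inhibitor of the sarcoplasmic reticulum calcium pump, stood at 11.24 ± 0.03 (SD, n = 2; 2427-fold; limma adjusted p = 0.00136). It was followed by Asb14 at 10.61 ± 0.07, Myot, a Z-disc protein, at 9.91 ± 0.07, Mylk4 at 9.73 ± 0.11, Tmem182 at 9.70 ± 0.18, Mybpc3, the cardiac myosin-binding protein C, at 9.66 ± 0.20, Txlnb at 9.63 ± 0.07 and Art3 at 9.41 ± 0.32. S100a8, a calcium-binding protein abundant in neutrophils, reached 9.38 ± 0.07. The rest of the top 15 were Tecrl (9.33 ± 0.34), Ces1d (8.88 ± 0.05), Plbd1 (8.59 ± 0.05), Ckmt2, the mitochondrial creatine kinase of muscle (8.57 ± 0.10), Corin, the protease that activates atrial natriuretic peptide (8.47 ± 0.04), and Lrrc2 (8.45 ± 0.10).

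The 15 lowest ratios lay between -9.49 and -7.19. Lox, the enzyme that cross-links collagen, was 720-fold lower in heart at -9.49 ± 0.15 (SD, n = 2; limma adjusted p = 0.00136). Rspo2, a secreted Wnt enhancer, was at -8.74 ± 0.34, Zic1, a zinc-finger transcription factor, at -8.55 ± 0.08, Mogat2 at -8.20 ± 0.35 and Cpa6 at -8.18 ± 0.46. Below these in size came the homeobox genes Hoxc9 (-7.99 ± 0.12), Hoxc6 (-7.72 ± 0.68) and Hoxb9 (-7.19 ± 0.22), Alkal1 (-7.81 ± 0.15), Grem1, a bone morphogenetic protein antagonist (-7.81 ± 0.09), Igf2bp3 (-7.55 ± 0.23), Col1a1 (-7.38 ± 0.02), Slc1a6 (-7.38 ± 0.20), Tnmd (-7.36 ± 0.92) and Spock3 (-7.26 ± 0.11). Of these 15, the adjusted p was at most 0.00483, and only Zic1, Hoxb9, Igf2bp3 and Col1a1 had more than 1 probe. The means of the 3 Col1a1 probes ran from -9.51 to -5.29.

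**Figure D2:**
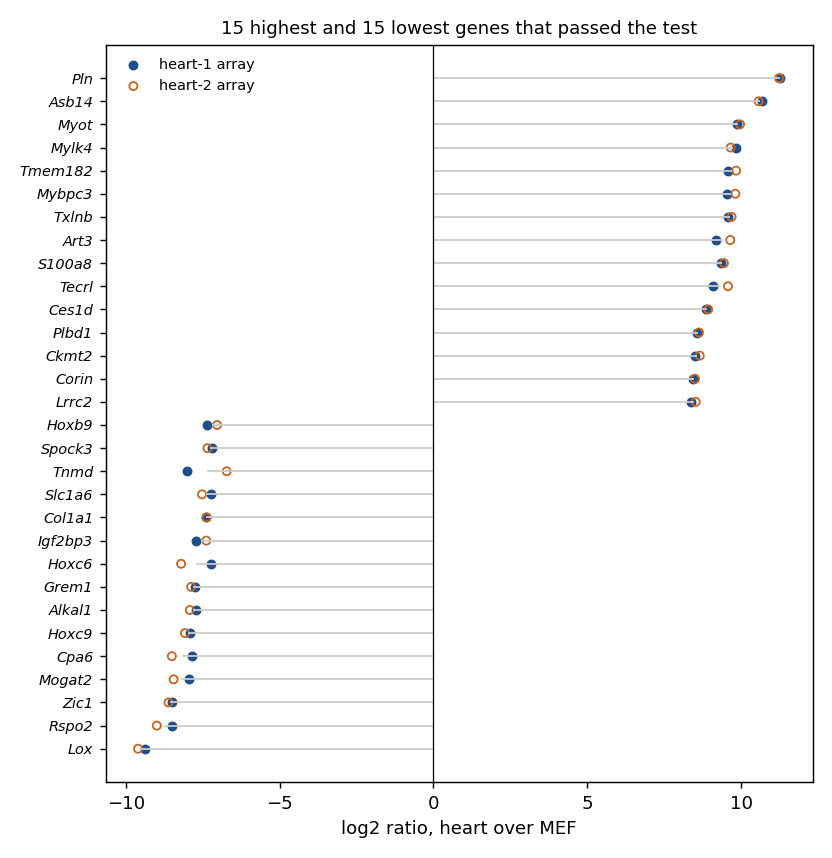
Log2 ratio of heart over MEF (x axis) of the 15 highest and 15 lowest genes that passed the test (y axis), with one point per array and a grey line from 0 to their mean. Pln reaches 11.24 and Lox -9.49; the arrays lie farthest apart for Tnmd, with an SD of 0.92.

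Genes of contraction and cardiac identity were mostly higher in heart. Of 22 measured sarcomere genes 22 rose, with Tnni3, cardiac troponin I, at 8.13 ± 0.11, Lmod2 at 8.06 ± 0.16, Myl7 at 7.31 ± 0.07, Myh6, the alpha myosin heavy chain, at 6.74 ± 0.06 and Myh7, the beta chain, at 5.77 ± 0.05; this list set the direction of the ratio, so its sign is not independent evidence. Of 32 genes of excitation-contraction coupling and ion channels 31 rose and 1 did not pass (median 3.70). Its members Hrc, Trdn and Abcc9 reached 8.26 ± 0.02, 7.21 ± 0.01 and 7.07 ± 0.26, with the 4 Trdn probes from 5.52 to 9.04. Atp2a2, the calcium pump itself, reached 3.85 ± 0.19 over 4 probes whose means ran from 0.84 to 7.41. Of 31 cardiac transcription factors 26 rose, 2 fell and 3 did not pass (median 2.17). Hopx (5.74), Ppara (5.51 ± 0.08), Nkx2-5 (5.06 ± 0.16) and Irx4 (29.9-fold higher) led, and Gata4 rose to 2.68 ± 0.03, over 2 probes at 1.00 and 4.37. Hand1 fell to -1.52 ± 0.03 and Isl1, a marker of cardiac progenitors, to -0.99 ± 0.06, while Tbx18 did not pass at -0.20 ± 0.38. Of 18 natriuretic peptide and stress genes 15 rose, 2 fell and 1 did not pass (median 3.23). The natriuretic peptides Nppa and Nppb stood at 5.50 ± 0.05 and 5.51 ± 0.12 and Xirp2 at 7.26 ± 0.04, whereas Ccn2, a matrix-associated growth factor, fell to -3.29 ± 0.02 and the metallothionein Mt2 to -0.70 ± 0.04. The camera adjusted p of these 4 lists was 2.59e-10, 9.95e-11, 8.71e-07 and 5.85e-05. With an estimated correlation the adjusted p was 0.36, 0.36, 0.41 and 0.39. That setting leaves camera 1 degree of freedom, here and for the lists below, and 0 of the 37 lists passed it. Adjusted over the list alone, the counts of the 4 lists were the same numbers.

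Genes of fatty acid oxidation, the respiratory chain, the tricarboxylic acid cycle and energy transfer were mostly higher in heart. All 30 measured genes of fatty acid oxidation rose (median 3.57), led by Ucp3 (7.36 ± 0.54), the fatty acid transporter Cd36 (6.45 ± 0.02), lipoprotein lipase Lpl (6.27 ± 0.09) and Pdk4, which inhibits pyruvate dehydrogenase (6.09 ± 0.09). Cpt1b, the muscle carnitine palmitoyltransferase, was 34.3-fold higher and Fabp3, the heart fatty-acid-binding protein, 32.1-fold. Of 58 genes of oxidative phosphorylation 57 rose and 1 fell (median 3.18), and all 57 also exceeded a 2-fold change by treat. The muscle forms Cox8b, Cox6a2 and Cox7a1 led at 8.39 ± 0.11, 6.77 ± 0.06 and 5.70 ± 0.10. The gene that fell was Cox8a, the ubiquitous counterpart of Cox8b, at -0.20 ± 0.05 with an adjusted p of 0.0479; it did not pass once the arrays were centred or scaled or the variance prior was made robust. All 22 genes of the tricarboxylic acid cycle list rose (median 2.95), with Mdh1 at 5.15 ± 0.06 and Idh3b 18.3-fold higher. Of 21 genes of creatine kinase, myoglobin and energy transfer 19 rose, 1 fell and 1 did not pass (median 3.36). The list as fixed also held the ADP-ribosyltransferases Art1 (7.20 ± 0.06) and Art3. Pygm, muscle glycogen phosphorylase, reached 8.04 ± 0.06, Ckm 6.13 ± 0.03 and myoglobin Mb 4.88 ± 0.03, while Ckb, the brain-type creatine kinase, fell to 2.78-fold below MEF. For these 4 lists the camera adjusted p was 2.12e-11, 7.57e-17, 2.26e-09 and 7.51e-07; with an estimated correlation the adjusted p was 0.36, 0.36, 0.36 and 0.39. The counts adjusted over the list alone were again the same.

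Glycolysis genes went both ways, and the list did not pass camera. Of 20 measured genes 10 rose, 6 fell and 4 did not pass, and adjusted over the list alone 11 rose and 7 fell (median 0.17, mean 0.61; camera adjusted p = 0.25). The muscle isoforms Pgam2 (7.01 ± 0.07), Eno3 (96.8-fold) and Pfkm (3.79 ± 0.05) rose, whereas Eno2 (-3.73 ± 0.09), Aldoc (-3.01 ± 0.14, with probes from -5.25 to -0.76) and the lactate exporter Slc16a3 (-4.22 ± 0.15) fell. Among genes chosen after their values were seen, Pgam1, the widely expressed counterpart of Pgam2, was 4.38-fold lower in heart, and the glucose transporters Slc2a4 and Slc2a1 stood at 7.03 ± 0.05 and -1.21 ± 0.04. Cholesterol synthesis was lower in heart, with 17 of 19 genes falling, 0 rising and 2 not passing (median -1.57). Sqle, the squalene epoxidase, fell to -5.01 ± 0.70, Cyp51 to -2.98 ± 0.14, Mvd to -2.46 ± 0.04 and Idi1 to -2.25 ± 0.26, and Hsd17b7 did not pass at 0.04 ± 0.04. Its camera adjusted p was 9.31e-05, and 0.36 was the adjusted p with an estimated correlation; adjusted over the list alone, 17 fell as well.

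Genes of the extracellular matrix were mostly lower in heart, with a few strong exceptions. Of 46 collagens and matrix proteins 38 fell, 7 rose and 1 did not pass (median -3.19). Beside Lox and Col1a1, Col5a2 fell to -7.11 ± 0.04, fibronectin Fn1 to -6.32 ± 0.36, Postn to -3.77 ± 0.11 and Col3a1 to -3.54 ± 0.32. The 2 Postn probes had means of -5.68 and -1.86, and the means of the 3 Col3a1 probes ran from -6.18 to -0.81. Rising members were Col15a1 (4.63 ± 0.17), a basement membrane collagen, the proteoglycan decorin, Dcn (3.59 ± 0.07), and Lama2, the laminin chain of muscle basement membrane (2.17 ± 0.04). Of 28 genes of collagen processing and matrix turnover 24 fell, 1 rose and 3 did not pass (median -2.38). The membrane metalloproteinase Mmp14 was at -5.84 ± 0.04, Timp1 at -5.49 ± 0.09, P4ha3 at -4.44 ± 0.28 and Pcolce at -4.32 ± 0.02; Timp4, an inhibitor of metalloproteinases, was the riser at 4.15 ± 0.07. Of 29 mesenchymal and fibroblast identity genes 24 fell, 3 rose and 2 did not pass, and adjusted over the list alone 25 fell (median -1.96). Foxd1 (-7.04 ± 0.90), Crabp1 (-6.94 ± 0.14), Prrx2 (-5.98 ± 0.04) and Cdh11 (-4.42 ± 0.04) fell the most, Thy1 was 10.1-fold and vimentin, Vim, 3.72-fold lower, and Dpt (3.99 ± 0.03), Tcf21, a transcription factor of cardiac fibroblasts (3.83 ± 0.06), and Cdh2 (2.54 ± 0.04) rose. These 3 lists had a camera adjusted p of 2.42e-06, 4.89e-06 and 6.18e-05; with an estimated correlation the adjusted p was 0.36 for each. Adjusted over the list alone, the first and second list kept the same counts.

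The actin and adhesion genes were mostly lower in heart as well. Of 31 members 26 fell, 4 rose and 1 did not pass, the same numbers as adjusted over the list alone (median -1.49; camera adjusted p = 6.18e-05, and adjusted p = 0.36 with an estimated correlation). Ccn1 was at -4.80 ± 0.02, Anxa1 at -3.31 ± 0.07 and Actg1, cytoplasmic gamma actin, at -3.40, while Ankrd1, a stretch-responsive gene of cardiac muscle, rose to 5.08 ± 0.06 and Cav1 to 1.79 ± 0.05. Pdlim5 rose as a mean of 5 probes (1.27) but fell as their median (-0.40). The smooth muscle and myofibroblast list did not pass (camera adjusted p = 0.0504), though it did with camera on ranks (adjusted p = 0.00855), with 14 of 20 genes falling and 6 rising under either adjustment, over all genes or adjusted over the list alone (median -1.39). Tagln (-4.76 ± 0.02), Cnn1 (-4.44 ± 0.02) and Actn1 (-3.62 ± 0.07) fell; desmin, Des (3.95 ± 0.02), Synpo2 (2.84 ± 0.06, over 4 probes whose means ran from -0.17 to 5.52) and Myh11, the smooth muscle myosin (1.61 ± 0.02), rose. Acta2, smooth muscle actin, stood at -1.46 ± 0.08 over 5 probes whose means ran from -5.01 to 3.10.

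Genes of cell division were mostly lower in heart. Of 41 mitosis genes 37 fell, 1 rose and 3 did not pass (median -3.27). Tpx2 (-4.66 ± 0.03), the checkpoint kinase Ttk (-4.60 ± 0.01), Hmmr (-4.39 ± 0.75) and Racgap1 (-4.27 ± 0.19) fell the most, and Mki67, the proliferation marker, was at -3.91 ± 0.02. Cenpf rose to 1.34 ± 0.01. Of 38 DNA replication genes 33 fell, 2 rose and 3 did not pass (median -1.75). The chromatin assembly factor subunits Chaf1b (-3.91 ± 0.04) and Chaf1a (-3.43 ± 0.09), Uhrf1 (-3.53 ± 0.17) and Mcm10 (-3.34 ± 0.02) led, and E2f2 rose to 2.19 ± 0.05. Of 23 D cyclin, CDK inhibitor and p53 target genes 16 fell, 5 rose and 2 did not pass, and adjusted over the list alone 17 fell (median -1.84). The lowest members were the CDK inhibitors Cdkn2b (-6.36 ± 0.09), Cdkn2a (-6.05 ± 0.03) and Cdkn1a (-4.87 ± 0.01). Other CDK inhibitors, looked up after their values were seen, varied. Cdkn2d rose to 0.56 ± 0.06, Cdkn1c fell to -2.48 ± 0.01, and Cdkn2c (-0.05 ± 0.04) and Cdkn1b (-0.46 ± 0.20) did not pass. In the same list cyclin D1, Ccnd1, was at -0.62 ± 0.03 and Perp (4.56 ± 0.01), Mycn (2.50 ± 0.01) and Sesn1 (2.30 ± 0.01) rose. For the 3 lists the camera adjusted p was 8.59e-08, 7.51e-07 and 0.00796; with an estimated correlation the adjusted p was 0.36, 0.36 and 0.39. Adjusted over the list alone, mitosis and DNA replication kept the same counts.

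Ribosomal protein genes and genes of endoplasmic reticulum chaperones and stress response were also mostly lower in heart. Of 47 cytosolic ribosomal protein genes 45 fell, 1 rose and 1 did not pass, and adjusted over the list alone 46 fell (median -1.17); ribosomal protein genes have many processed pseudogenes that can share a probe's sequence. Rpl3 was at -2.56, Rps20 at -2.11 ± 0.04 and Rps12 at -2.04 ± 0.03, and Rpl30 rose to 0.30 ± 0.05, a call lost once the arrays were centred. Of 23 genes of endoplasmic reticulum chaperones and stress response 20 fell, 2 rose and 1 did not pass, under either adjustment, over all genes or adjusted over the list alone (median -1.31). The members that moved most are targets of the amino acid and integrated stress response, Asns (-5.52 ± 0.01), Chac1 (-4.30 ± 0.03), Trib3 (-4.23 ± 0.16) and their regulator Atf4 (-2.46 ± 0.07), and Herpud1 rose to 1.86 ± 0.04. The camera adjusted p was 6.11e-09 and 6.42e-05; with an estimated correlation the adjusted p was 0.36 for both.

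Genes of embryonic patterning and fetal growth were mostly lower in heart. Of 37 Hox genes 33 fell, 1 rose and 3 did not pass (median -2.15). The lowest after Hoxc9, Hoxc6 and Hoxb9 was Hoxa11 at -6.56 ± 0.13; Hoxb1 rose to 0.63 ± 0.02. Of 24 imprinted and fetal growth genes 19 fell, 3 rose and 2 did not pass (median -2.44). Igf2, the fetal growth factor, was 49.2-fold lower, its neighbouring non-coding RNA H19 38.6-fold lower, and Igf2bp1, an RNA-binding protein of fetal tissues, was at -5.82 ± 0.10; the risers were led by Dcn and by Snrpn at 1.29. The camera adjusted p was 2.48e-07 and 3.05e-04; with an estimated correlation the adjusted p was 0.36 for both. Adjusted over the list alone, the counts of both lists were the same. The pluripotency list did not pass (camera adjusted p = 0.93; median 0.02, mean -0.31). Of its 23 genes 7 rose, 6 fell and 10 did not pass, and adjusted over the list alone 5 rose and 6 fell. Nanog was at 0.02 ± 0.21 and Pou5f1 at -0.27 ± 0.49, neither passing. Sox2 (-4.27 ± 0.06) and Dppa3 (-3.26 ± 0.07) fell and Esrrb, which is also on the cardiac transcription factor list, rose to 3.45 ± 0.21, with probes from 0.45 to 6.46.

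Markers of several other cell types of the heart and of blood were mostly higher in heart. All 27 endothelial genes rose (median 4.34), with vascular endothelial cadherin Cdh5 at 7.53 ± 0.02, Sox18 at 6.23 ± 0.09, Fabp4 at 5.94 ± 0.13, Mmrn2 at 5.80 ± 0.28 and Pecam1 at 3.21 ± 0.14. Of 11 erythroid genes 9 rose and 2 did not pass (median 2.66). Alas2, which starts haem synthesis in red cells, was at 6.58 ± 0.08, Hba-a1 at 6.27 ± 0.08, Rhd at 5.04 ± 0.08 and the embryonic globin Hbb-y at 6.18 ± 0.19. Some globin genes are similar in sequence, so whether the Hbb-y probe reads that gene alone is not known here. Klf1 (-0.40 ± 0.32) and the embryonic Hba-x (-0.02 ± 0.36) did not pass. Of 18 lymphocyte genes 15 rose and 3 did not pass (median 1.69), led by Cd79b of B cells (4.99 ± 0.03), Klrd1 of natural killer cells (4.80 ± 0.46), Ms4a1 (4.12 ± 0.21) and Jchain (3.59 ± 0.27). Of 15 adipocyte genes 10 rose, 3 fell and 2 did not pass (median 1.79), with Cidea at 6.38 ± 0.13, Plin4 at 5.47 ± 0.01 and Adipoq at 4.60 ± 0.82 against Fasn at -2.01 ± 0.01 and Cebpa at -1.94 ± 0.07. The camera adjusted p of these 4 lists was 2.59e-10, 5.54e-04, 1.13e-04 and 0.0206; with an estimated correlation the adjusted p was 0.36, 0.45, 0.36 and 0.38. Their counts adjusted over the list alone were the same.

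Several other cell type lists were split. Of 24 macrophage and myeloid genes 15 fell, 7 rose and 2 did not pass, and adjusted over the list alone 8 rose (median -1.04, mean 0.35; camera adjusted p = 0.15). The 4 largest rises were those of S100a8, S100a9 (7.53 ± 0.31), also of neutrophils, Cd163 (6.67 ± 0.51) and Lyve1 (5.84 ± 0.12), which mark resident tissue macrophages, Lyve1 also lymphatic vessels. Among fallers chosen after their values were seen, Cd14 was at -3.21 ± 0.02, lysozyme Lyz2 at -2.32 ± 0.01 and the complement subunit C1qa at -2.06 ± 0.02. Of 26 skeletal muscle genes 15 rose, 8 fell and 3 did not pass, the same as adjusted over the list alone (median 0.61; camera adjusted p = 0.0644, and 0.0476 on ranks). Myl1 (6.28 ± 0.13), Myh4 (5.33 ± 0.19) and Mybpc2 (5.17 ± 0.09) rose, and Actn3 (-1.83 ± 0.03), Tnnt3 (-1.40 ± 0.08) and the myogenic regulator Myod1 (-1.04 ± 0.05) fell. Of 13 epicardial and mesothelial genes 8 rose, 3 fell and 2 did not pass, with 9 rising adjusted over the list alone (median 1.02; camera adjusted p = 0.074); Rspo1 was at 2.77 ± 0.12 and Upk3b at 2.59 ± 0.86. Of 16 neuronal and Schwann genes 4 rose, 8 fell and 4 did not pass, with 9 falling adjusted over the list alone (median -0.34; camera adjusted p = 0.30). Gap43, a growth cone protein, fell to -3.99 ± 0.21, and Mal rose to 4.33 ± 0.39, with probes from 2.23 to 6.43.

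Immune genes moved both ways. Of 20 genes of antigen presentation and complement 16 rose, 2 fell and 2 did not pass (median 1.54). The class II genes H2-Aa (5.46 ± 0.17), H2-Ab1 (5.04 ± 0.06) and H2-Eb1 (3.72 ± 0.09) and the invariant chain Cd74 (4.78 ± 0.02) led, beside the rise of lymphocyte markers, and Tap1 fell to -1.14 ± 0.05. Of 29 chemokine, cytokine and interferon response genes 20 fell, 6 rose and 3 did not pass (median -0.82). The prostaglandin synthase Ptgs2 was at -6.13 ± 0.17, interleukin 6, Il6, at -4.15 ± 0.16 and Ccl2 at -3.62 ± 0.02, while the chemokines Ccl11 and Ccl8 rose to 5.27 ± 0.08 and 2.36 ± 0.10. The camera adjusted p was 3.63e-05 and 0.00901; with an estimated correlation the adjusted p was 0.36 for both. Both lists had the same counts adjusted over the list alone.

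**Figure D3:**
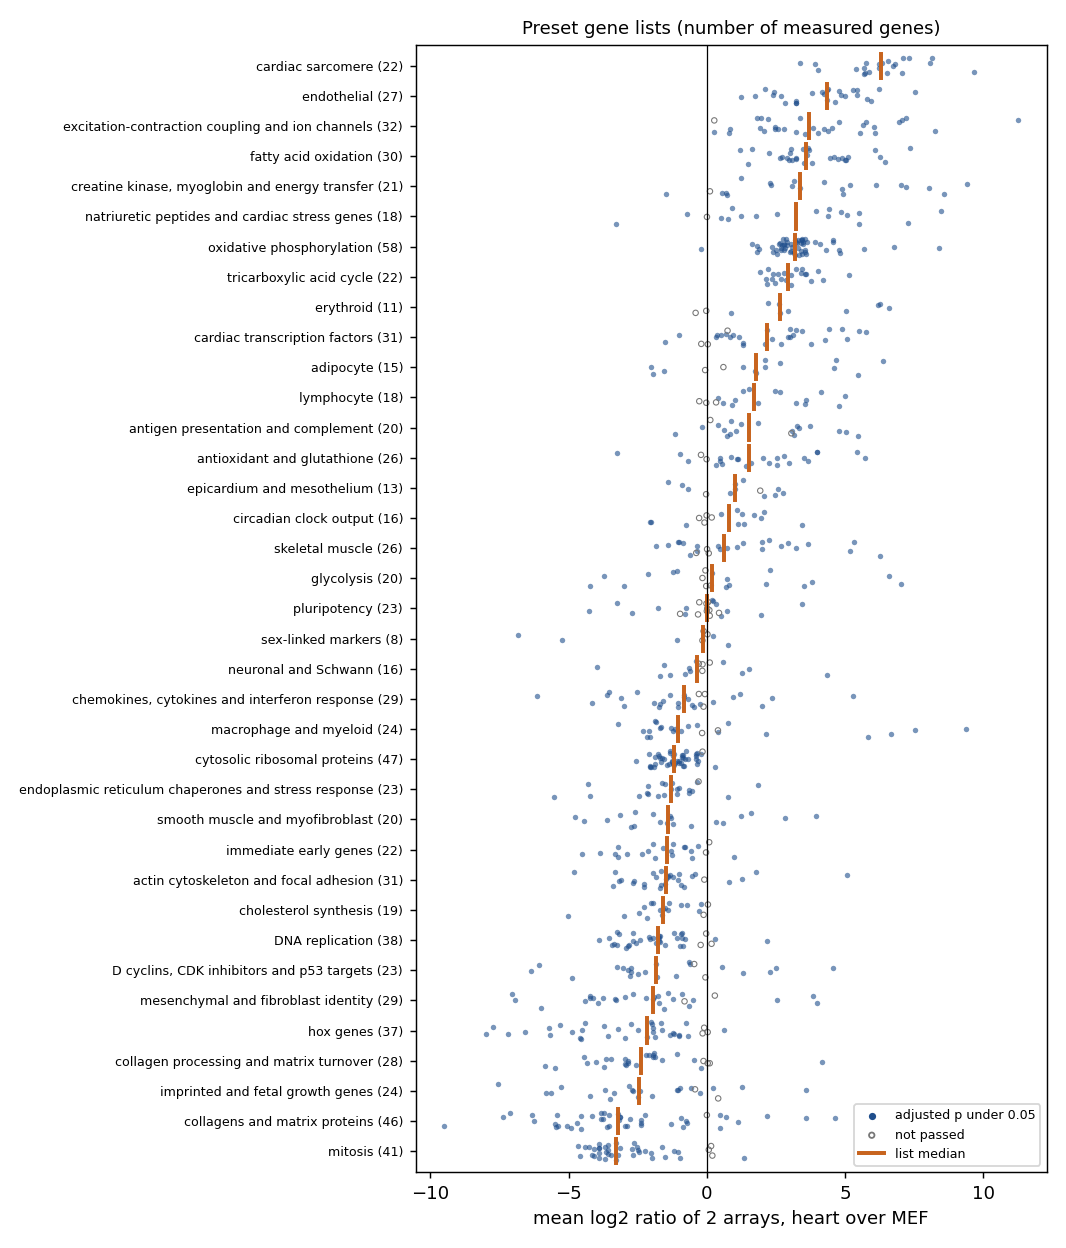
Mean log2 ratio of heart over MEF (x axis) of each member of the 37 gene lists (y axis, number of measured genes in brackets), filled where the adjusted p was under 0.05 and open otherwise, with the list's median as a bar; vertical scatter within a list only separates the points. Medians run from -3.27 for mitosis to 6.28 for the cardiac sarcomere.

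Across the 37 lists, 28 passed camera with its preset correlation, 14 higher and 14 lower in heart. With an estimated correlation camera has 1 degree of freedom here, and 0 lists passed, 0 of them even at an unadjusted p under 0.05 (lowest unadjusted p = 0.0851). Lists with a negative estimated correlation failed there too, among them the tricarboxylic acid cycle (-0.013) and mitosis (-0.0195). The loss therefore need not reflect correlation between genes. On ranks camera passed 30 lists. The fry test, which asks whether the genes of a list move on balance one way and does not compare them with other genes, passed 37 of 37 lists, glycolysis (higher, adjusted p = 0.00411) and pluripotency (lower, adjusted p = 0.00822) among them.

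The hearts were also set against each other, with no test because each was measured once. The log2 ratios differed at least 2-fold in 406 genes (2.08%), of which 166 were higher in heart-1 and 240 in heart-2. The largest differences were 3.80 for Nxph2, 2.90 for Chst5, 2.90 for Krtap19-4, 2.57 for Gm31063 and 2.56 for Dync1i1 in favour of heart-1, and -3.25 for Kif6, -3.16 for Armt1, -2.96 for Vmn1r24, -2.57 for Fam83d and -2.54 for Ciita, each a heart-1 value minus its heart-2 value. All 10 rest on 1 probe each, as do 373 of the 406 genes (91.9%), against 56.4% of all genes.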

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

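The alternatives that left out the spike of near-constant values or read the values as natural logarithms were chosen after seeing the data. Of the 14283 genes called, the count fell to 5797 when tested against a 2-fold change and to 6131 without shared variance, and was 23582 with every named probe tested on its own, because 32664 probes were then tested; under the other alternatives run (centring, scaling, robust prior, median of probes, probes of one sign, spike left out) it lay between 12399 and 14591, with 45.7% to 48.2% of calls higher in heart. Both ends of that range come from fewer genes. The 12399 were of 16208 genes whose probes share 1 sign, and the 14591 of 17311 genes with the spike left out. Over all 19532 genes the count lay between 13073 (centred) and 14289 (scaled). Centring subtracted a median of 0.07 from heart-1 and of -0.14 from heart-2, and the latter lies inside the spike. It moved the arrays apart for most genes, and limma then fitted 1 variance for every gene (infinite prior degrees of freedom, prior SD 0.269 against 0.066). The 13073 calls and the 31 lists after centring therefore rest on that variance and are no independent check, and 9 of the 10 genes that differed most between the hearts gained a call there. The 7140 genes at least 2-fold apart on both arrays became 3163 at 4-fold and 12583 with every named probe on its own, and 7734 to 7766 on either array alone; a single array allows no test. Read as natural logarithms the values gave 9431 such genes. For heart-1 against heart-2, the 406 genes at least 2-fold apart became 963 with every named probe on its own, 40 at 4-fold and 914 as natural logarithms. The correlation between the arrays stayed between 0.980 and 0.986. Of the 28 gene lists that passed, 0 passed with an estimated correlation, which leaves 1 degree of freedom, while the other list tests and settings passed 28 to 37. Among the named genes and lists, 5 values changed sign in settings that kept both arrays: the pluripotency list (-0.14 without the spike), Blk (0.0166) and Hba-x (0.0154) after centring, and Xist (0.0933) and Pdlim5 (-0.40) with the median of their probes. Of these, Pdlim5 was called both ways, because its 5 probes disagree. The others passed in neither setting. On a single array, further named genes had the sign opposite to their mean. Among them were Nxph2 (mean 1.70, but -0.20 on heart-2) and Armt1 (mean 0.52, but -1.06 on heart-1). Of 260 named genes, 68 lost their call without shared variance and 23 against a 2-fold change. No paired analysis was possible because the arrays form 1 group. The deposited ratios carry no intensities, so signal over background could not be used to set a limit.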

Other observations

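Further lists fixed before the data were examined covered clock, stress and detoxification genes. Of 16 circadian genes 9 were higher in heart, 3 were lower and 4 did not pass, with 10 higher when adjusted over the list alone (median 0.81; camera adjusted p = 0.0711). The output factor Hlf stood at 3.44 ± 0.07 and Ciart at 2.07 ± 0.09, against the clock activator Arntl, 4.01-fold lower in heart, and the repressor Nfil3 at -2.05. Of 26 antioxidant and glutathione genes 21 were higher, 3 were lower and 2 did not pass, with 4 lower when adjusted over the list alone (median 1.51; camera adjusted p = 6.18e-05, and adjusted p = 0.36 with an estimated correlation). Gsta1 (5.73 ± 0.53), Gsta3 (5.45 ± 0.08), Mgst3 (3.98 ± 0.06) and mitochondrial superoxide dismutase, Sod2 (3.97 ± 0.11), led, and haem oxygenase, Hmox1, was lower at -3.24 ± 0.05. Glutathione transferases of one class are similar in sequence, so their probes cannot be taken to tell them apart. Of 22 immediate early genes 19 were lower in heart, 1 was higher and 2 did not pass, the same as adjusted over the list alone (median -1.43; camera adjusted p = 7.83e-05, and adjusted p = 0.36 with an estimated correlation). Egr1 was at -4.51 ± 0.08, Ier2 at -3.86 ± 0.06 and Fos at -3.32 ± 0.42, the last over 2 probes at -5.24 and -1.39. Fosb was the exception at 0.97 ± 0.14. Of 8 sex-linked genes 2 were higher in heart, 3 were lower and 3 did not pass, the same as adjusted over the list alone (median -0.14; camera adjusted p = 0.45).

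The tests in the next paragraphs were chosen after the patterns were seen. The spike of near-constant values held 13.0% of probes on heart-1 and 15.2% on heart-2, and 3644 probes lay in it on both arrays. If all probes of an array share one zero, equal levels in heart and MEF do not account for it. Its centers lie 0.31 apart on the log2 scale, while probes outside it differ by a median of -0.01 between arrays. The normalization is not known, so a separate offset of these probes on each array cannot be excluded. Values set by the processing for probes without signal are a candidate explanation: probes of olfactory and vomeronasal receptors, genes of sensory neurons, lay in the spike on both arrays in 13.9% of cases, against 5.97% of other named probes (Fisher's exact test, two-sided, p = 6.15e-21), and probes without a gene name in 18.9%. Most of the 1097 receptor probes did not lie in the spike on both arrays, which this candidate leaves unexplained. If the candidate holds, a ratio near 0 may hold no measurement for the 871 genes with every probe in the spike on both arrays. No intensity was used here to check that.

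In 228 pairs of probes of the same gene whose first probe differed at least 2-fold between heart-1 and heart-2, the second went the same way in 56.6% (95% Clopper-Pearson interval 49.9% to 63.1%), by a median of 0.0187 where the first probe's was 1.24. In these pairs the differences thus mostly did not repeat, as noise of single probes would give, though 10 of them did repeat at least 2-fold. Probes in the spike were kept, and where both arrays hold the spike their difference is near-constant (SD 0.025). Such a second probe differs by about 0.31 in favour of heart-1 whatever the first does. It counts as going the same way only where the first is higher in heart-1. The share and the median above carry this fixed offset. Probes of a gene also correlated at only 0.605 in their mean ratios. A difference in the genes' RNA is therefore not excluded. The 373 of 406 genes at least 2-fold apart that have 1 probe could not enter this test, and their differences stay open. Over 758 pairs with both probes at least 4-fold from MEF, the differences, freed of a linear trend on the mean ratio, had a correlation of -0.0384 (95% interval -0.109 to 0.0329) between probes; over 1 pair from each of 8511 genes it was 0.0231 (95% interval 0.00185 to 0.0443), small but above 0, without removing a trend, against 0.605 for the mean ratios. Spike probes were kept in the 8511 pairs. Pairs with both probes in the spike on both arrays share a difference near 0.31, which can raise that correlation above 0. Whether the arrays held the same heart RNA or separate hearts that are very alike could not be told from these correlations. In the first case the p-values would describe technical error alone.

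Some Y-linked transcripts were far lower in heart, and others were not. Eif2s3y was at -6.84 ± 0.14, Kdm5d at -5.23 ± 0.62 and Uty at -1.06 ± 0.13 as a mean of 4 probes, the lowest at -2.78. Zfy1 was higher in heart at 0.77 ± 0.09, with its 2 probes at -0.11 and 1.66, and Usp9y (0.02 ± 0.21) and, chosen after its values were seen, Sry (-0.12 ± 0.08) did not pass. The labels give no sex, and female hearts set against MEF that are all male would need Xist, the RNA of the inactive X chromosome, to be far higher in heart, but its highest probe was at 0.52. Female hearts against MEF of both sexes may account for the low Y-linked transcripts and the Xist values, though not for Zfy1, with a median Xist probe of 0.0933, yet the 4 Xist probes ran from -1.34 to 0.52 and do not share a sign, which leaves this open.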
